A study of Homo sapiens with 4 samples.

How the data were processed

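Polyadenylated RNA of BEAS-2B, an established human bronchial epithelial cell line grown in N2B27 medium, was sequenced in 4 libraries. Per the labels, 2 libraries came from cells with a control short hairpin RNA (shRNA) and 2 from cells with an shRNA against Fer. Total RNA was treated with DNase, selected on oligo(dT) beads and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited a table of raw read counts per gene, with gene identifiers, symbols and lengths, per the file headers. Per the submitters' processing notes, HISAT2, featureCounts and DESeq2 were named, as were the genome builds hg19 and mm10, without versions or roles. The strand setting and the annotation release are not given in the sources used here.

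The table held 39635 entries. Of these, 1 row held no values and was left out, and 23979 of the other 39634 had a total count above 0. Library totals ran from 21422976 to 25169713 counts. For 3 libraries the column carries a name that the labels give. The column of replicate 1 of Fer knockdown carries a shorter form, and it was matched as the only knockdown library with that number. Symbols were taken from the table, in which 883 were duplicated, so genes were followed by identifier. The length column was not used. Transcript lengths, GC content, gene types, chromosomes and exon overlaps came from GENCODE release 29, which matched 39581 identifiers and 15329 of the 15336 tested genes (99.95%). That release belongs to another build than hg19, so chromosomes are given without coordinates. An overlap with exons of other genes is given as a percent of a gene's exonic bases on either strand, since reads of overlapping genes cannot be told apart without strand.

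Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, which left 15336, and libraries were scaled by TMM factors (0.940 and 0.949 for the controls, 1.06 and 1.06 for the other 2 libraries). Expression is given as CPM on that scale. The difference between the groups was tested with edgeR's quasi-likelihood test, two-sided, without a block, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are the libraries labelled Fer knockdown over control. Their standard errors (SE) were taken from the fold change and the test statistic. The model had 2 residual degrees of freedom.

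Before the data were examined, 43 gene lists, the test, the rule for named genes and most of the alternatives were written down. The rule took FER, then the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 5 CPM in the higher group. Both libraries of a group had to lie on the same side of the other group, and names of clones, pseudogenes, antisense and read-through genes, and any name ending in P and digits, were left out. The last part also left out MT-ATP6, which is not a pseudogene. For each list it took up to 4 members past the threshold in order of p, or, where a list had none, up to 2 with the smallest p. Any other gene named is said to be chosen after its values were seen. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on the edgeR model, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with a correlation estimated per list and fry, which tests whether the members move one way on balance without comparing them with other genes, were the alternatives.

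The other alternatives were the replicate number as a block, scaling by DESeq2 size factors, by upper-quartile factors or by library totals alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 5 CPM in 2 libraries, a test against a 1.5-fold change (glmTreat), and each library left out in turn. With a library left out, its group holds 1 library, which is assumed to vary like the 2 of the other group. Leaving out the genes of the mitochondrial chromosome, and removing trends on transcript length and GC content from each library (lowess, span 0.3), were added after seeing the data. The steps were tested on simulated counts for this comparison, in a fit of 15093 genes with 200 changed. The test recovered 31 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 11 calls among unchanged genes. With no gene changed it made 0 calls. The simulated libraries had the same spread in both groups, and the changed genes all had an average log2 CPM above 2. In the real data the median SD of log2 CPM was 0.184 in control and 0.0829 in the libraries labelled Fer knockdown. The simulated recovery and false calls may therefore not carry over to these data.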

Results

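The series asked how depletion of FER, a cytoplasmic tyrosine kinase, alters gene expression in the human bronchial epithelial line BEAS-2B. Raw read counts of 2 libraries with a control shRNA and 2 libraries labelled Fer knockdown were compared. The control libraries held 21772587 and 22857051 counts, and the libraries labelled Fer knockdown held 21422976 and 25169713. Between 20284 and 20944 genes had at least 1 count in a library. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals on shares of counts cover counting error only.

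FER mRNA was not lower in the libraries labelled Fer knockdown. FER (ENSG00000151422, chromosome 5) had 334 and 459 counts in the control libraries and 404 and 535 counts in the libraries labelled Fer knockdown. On the scaled values this was 18.8 ± 3.42 CPM in control and 19.0 ± 1.66 CPM in the libraries labelled Fer knockdown (SD, n = 2 each). The log2 fold change was 0.02 ± 0.17 (SE), with a 95% interval of -0.37 to 0.40 and an adjusted p of 0.976 in edgeR's quasi-likelihood test. No exon of another gene overlaps FER. The column of replicate 1 of Fer knockdown was matched from a shortened name. The FER mRNA level goes against the knockdown label, and each direction below is that of the libraries labelled Fer knockdown against control. In the list of FER, its relative FES and known partners, FES itself was too low to be tested, and of the 17 tested genes 0 passed over all genes and 0 when adjusted over the list alone, with a median log2 fold change of -0.01 (camera adjusted p = 0.937). The closest members were JUP, which encodes the junction protein plakoglobin, at -0.46 (adjusted p = 0.0960), and CTTN, which encodes the actin-binding FER substrate cortactin, at 0.27 (adjusted p = 0.238).

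**Figure D1:**
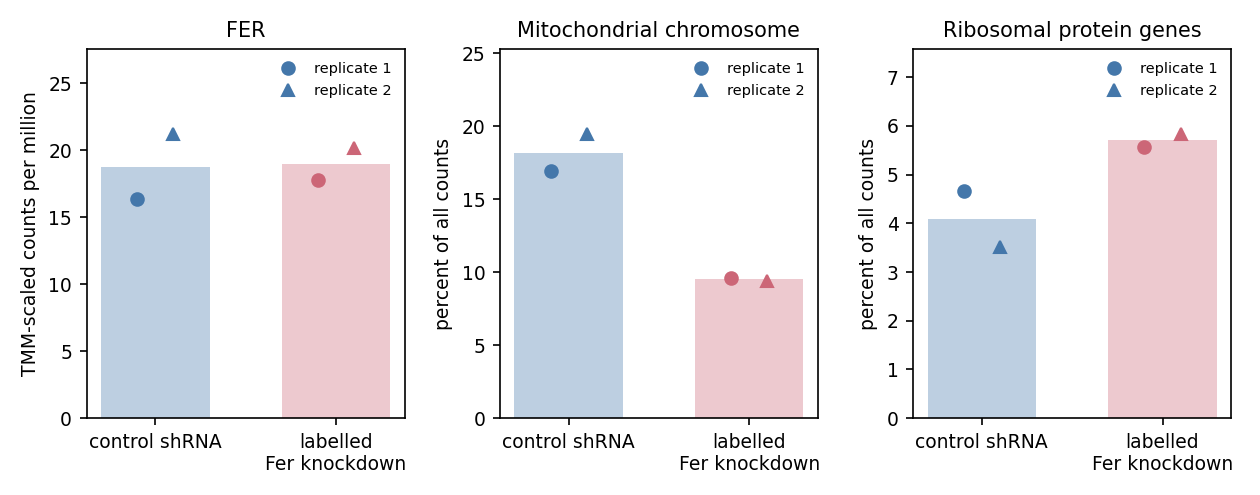
FER expression (TMM-scaled CPM), the percent of counts on the mitochondrial chromosome and the percent of counts in 86 ribosomal protein genes. Symbols are single libraries and bars are means of 2 libraries. FER was 18.8 CPM in control and 19.0 CPM in the libraries labelled Fer knockdown, while the mitochondrial share was 18.2% and 9.50%.

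Of 15336 genes, 99 passed an adjusted p of 0.05, with 43 higher and 56 lower, and 15 of the 56 lie on the mitochondrial chromosome. Changes of more than 2-fold were found for 30 of the higher genes and 19 of the lower ones. Scaling by library totals alone called 443 genes, 396 higher and 47 lower, and moved the median log2 fold change of all genes from 0.01 to 0.18. The control libraries differed more from each other (median absolute log2 difference of 0.26 over genes) than the libraries labelled Fer knockdown did (0.117). Without control replicate 1 the test called 4734 genes and without control replicate 2 it called 3298, and both sets held all 99. Without replicate 1 of the libraries labelled Fer knockdown it called 114, which held 53 of the 99, and without replicate 2 it called 56, which held 30.

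The 13 mRNAs encoded by the mitochondrial genome, which specify subunits of the respiratory chain and ATP synthase, were lower as a group. Of the 13, 12 fell over all genes and 13 when adjusted over the list alone, with a median log2 fold change of -1.12 (camera adjusted p = 1.31e-52). With an estimated correlation the call was lost (adjusted p = 0.443 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, went from 20520 ± 949 to 8464 ± 313 CPM (SD, n = 2 each), a log2 fold change of -1.28 ± 0.10 (SE, adjusted p = 0.00128). MT-CO1, of the same complex, fell by 1.10 on the log2 scale (adjusted p = 0.00339) from 44330 to 20700 CPM. MT-CO3 fell by 1.12 and the complex I subunits MT-ND1, MT-ND2 and MT-ND4 fell by 1.25, 1.27 and 1.21, each with an adjusted p of 0.00128. MT-CYB, of complex III, fell by 1.07 (adjusted p = 0.00240), and MT-ND4L, which shares 2.36% of its exonic bases with MT-ND4, fell by 1.16 (adjusted p = 0.0302). The transfer RNA gene MT-TP fell by 1.38 (adjusted p = 0.0159). MT-ATP6, which the naming rule left out and which was chosen after its values were seen, fell by 1.15 (adjusted p = 0.00139, 6.90% exon overlap). All counts on the mitochondrial chromosome made up 16.9% (95% Wilson interval 16.89 to 16.92) and 19.4% (19.41 to 19.45) of the control libraries. They made up 9.62% (9.607 to 9.632) and 9.37% (9.361 to 9.384) of the libraries labelled Fer knockdown.

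Genes of the cytosolic ribosome and nuclear genes of oxidative phosphorylation were higher as groups at the preset correlation. Of 30 tested ribosomal protein genes, 4 rose and 0 fell over all genes, and 11 rose when adjusted over the list alone, with a median log2 fold change of 0.33 (camera adjusted p = 3.76e-10, and adjusted p = 0.754 with an estimated correlation). RPS12 went from 216 ± 56.4 to 567 ± 72.0 CPM (SD, n = 2 each), a log2 fold change of 1.39 ± 0.18 (SE, adjusted p = 0.0157). RPS29 rose by 1.72 (adjusted p = 0.0182, 8.85% exon overlap), RPLP1 by 1.02 (adjusted p = 0.0302), RPL34 by 1.05 (adjusted p = 0.0347) and RPS21, among the largest increases of all genes, by 1.49 (adjusted p = 0.0193). Of 21 nuclear oxidative phosphorylation genes, 2 rose and 0 fell over all genes, and 11 rose when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 8.8e-09, and adjusted p = 0.729 with an estimated correlation). COX7C, a subunit of cytochrome c oxidase, rose by 1.02 (adjusted p = 0.0378) and NDUFA4 by 0.92 (adjusted p = 0.0378). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. All 86 ribosomal protein genes made up 4.67% (95% Wilson interval 4.66 to 4.678) and 3.51% (3.506 to 3.521) of the counts of the control libraries. They made up 5.58% (5.567 to 5.586) and 5.83% (5.818 to 5.836) of those of the libraries labelled Fer knockdown, in which the mitochondrial share was lower. Leaving out the mitochondrial chromosome left the 2 list medians at 0.32 and 0.39 (camera adjusted p = 1.69e-09 and 1.73e-08). The ribosomal median was 0.56 without control replicate 1 and 0.13 without control replicate 2, and the respiratory chain median was 0.60 and 0.20. Without replicate 2 of the libraries labelled Fer knockdown, RPL34, COX7C and NDUFA4 lost their calls (adjusted p = 0.124, 0.152 and 0.30).

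Host genes of small nucleolar RNAs and other abundant non-coding RNAs were also higher as a group. Of 12 tested, 3 rose and 0 fell over all genes, and 7 rose when adjusted over the list alone, with a median log2 fold change of 0.59 (camera adjusted p = 8.8e-09, and adjusted p = 0.443 with an estimated correlation). NEAT1, the RNA scaffold of nuclear paraspeckles, went from 1636 ± 125 to 2691 ± 102 CPM (SD, n = 2 each), a log2 fold change of 0.72 ± 0.11 (SE, adjusted p = 0.0302). SNHG8 rose by 1.55 (adjusted p = 0.0182), with 14.2% of its exonic bases shared with a small nucleolar RNA. EPB41L4A-AS1 rose by 0.95 (adjusted p = 0.0378), and 49.6% of its exonic bases overlap EPB41L4A, so its counts are uncertain. NEAT1 and EPB41L4A-AS1 lost their calls without replicate 1 of the libraries labelled Fer knockdown (adjusted p = 0.0999 and 0.127) and without replicate 2 (0.309 and 0.192). The mitochondrial share was lower and the ribosomal share higher in the same libraries. Leaving out the mitochondrial chromosome left the list median at 0.58 (camera adjusted p = 1.73e-08).

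Mesenchymal genes and genes of the actin cytoskeleton were lower as groups in the libraries labelled Fer knockdown. Of 19 tested mesenchymal and epithelial-mesenchymal transition genes, 2 fell and 0 rose over all genes, and 8 fell when adjusted over the list alone, with a median log2 fold change of -0.37 (camera adjusted p = 2.14e-06, and adjusted p = 0.443 with an estimated correlation). MMP2, a gelatin-cleaving matrix metalloproteinase, went from 245 ± 6.37 to 132 ± 11.3 CPM (SD, n = 2 each), a log2 fold change of -0.90 ± 0.12 (SE, adjusted p = 0.0182). THY1, a cell surface glycoprotein of fibroblasts, fell by 0.77 (adjusted p = 0.0302, 10.7% exon overlap). Of 23 actin cytoskeleton and serum response factor target genes, 2 fell and 0 rose over all genes, and 8 fell when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 9.33e-05, and adjusted p = 0.443 with an estimated correlation). The actin monomer-binding gene PFN1 fell by 0.61 and the tropomyosin gene TPM4, with 9.60% exon overlap, by 0.62 (adjusted p = 0.0461 each). All 4 named genes lost their calls when either library labelled Fer knockdown was left out (adjusted p = 0.0568 to 0.617), and the mesenchymal median was -0.17 without control replicate 2. With library totals alone, where the median of all genes was 0.18, the list medians were -0.20 and -0.05, and PFN1 and TPM4 lost their calls (adjusted p = 0.0542 and 0.0549). The mitochondrial share of counts was lower in the same libraries. With the mitochondrial chromosome left out, the medians were -0.37 and -0.22 (camera adjusted p = 2.14e-06 and 9.97e-05). These 2 list calls therefore did not rest on the mitochondrial counts, although PFN1 and TPM4 then missed the threshold (adjusted p = 0.0521 and 0.0515).

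Genes for matrix-cleaving proteases and their inhibitors, targets of TGF-beta, and integrins were also lower as groups. The mitochondrial share of counts was lower in the same libraries labelled Fer knockdown (9.50% against 18.2% in control). Of 22 protease and inhibitor genes, 0 passed over all genes, and 5 fell and 0 rose when adjusted over the list alone, with a median log2 fold change of -0.25 (camera adjusted p = 0.00212, and adjusted p = 0.633 with an estimated correlation). SERPINE2, which inhibits serine proteases, and PLAT, the tissue plasminogen activator, were at -0.62 and -0.52 (adjusted p = 0.0639 and 0.0725). The median of this list was -0.11 without control replicate 2 and -0.08 with library totals alone. Of 18 TGF-beta target genes, 2 fell and 0 rose over all genes, and 4 fell when adjusted over the list alone. Their median was -0.14 (camera adjusted p = 0.0251, and adjusted p = 0.509 with an estimated correlation), but 0.03 with library totals alone, where that of all genes was 0.18 and the call was lost (adjusted p = 0.0501). The cytokine gene TGFB1 fell by 0.64 ± 0.11 (SE, adjusted p = 0.0436), from 247 ± 7.05 to 158 ± 2.10 CPM (SD, n = 2 each), and the matrix protein gene TGFBI fell by 0.60 (adjusted p = 0.0461). Of 23 integrin and focal adhesion genes, 0 passed over all genes and 0 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0485, and adjusted p = 0.848 with an estimated correlation). With the replicate number as a block the integrin list missed the threshold (camera adjusted p = 0.052). ZYX and ITGA5, for zyxin and the fibronectin receptor subunit, were at -0.42 and -0.35 (adjusted p = 0.121 and 0.167). The TGF-beta call was lost without replicate 1 of the libraries labelled Fer knockdown, where its median was -0.09 (adjusted p = 0.233), and with a filter of 5 CPM (0.0521), and its median was -0.21 without control replicate 2. TGFB1 and TGFBI lost theirs without either library labelled Fer knockdown (adjusted p = 0.507 to 0.705) and with library totals alone (0.0533 and 0.0549). The integrin call was lost without control replicate 2, where its median was -0.08 (adjusted p = 0.404), without replicate 1 or 2 of the libraries labelled Fer knockdown (0.106 and 0.128), with a filter of 5 CPM (0.0518) and with library totals alone, where its median was -0.01 (0.123).

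Epithelial genes and genes of NF-kB signalling and inflammation were higher as groups, with 0 members past the test over all genes in each. Of 23 epithelial junction and identity genes, 2 rose and 0 fell when adjusted over the list alone, with a median log2 fold change of 0.23 (camera adjusted p = 0.0200, and adjusted p = 0.509 with an estimated correlation). F11R and TJP3, which encode tight junction proteins, were at 0.51 and 0.92 (adjusted p = 0.0924 and 0.110), and 36.6% of the exonic bases of F11R overlap another gene. Of 22 NF-kB and cytokine genes, 6 rose and 1 fell when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0137, and adjusted p = 0.509 with an estimated correlation). The neutrophil chemokine CXCL8 was at 0.81 ± 0.20 (SE, adjusted p = 0.0924), from 15.6 ± 4.22 to 27.4 ± 4.23 CPM (SD, n = 2 each), and the growth factor CSF2 at -0.89 (adjusted p = 0.0924). The epithelial call was lost without control replicate 1 or 2 (adjusted p = 0.434 and 0.0939), without replicate 1 or 2 of the libraries labelled Fer knockdown (0.133 and 0.0629), in DESeq2 (0.0684), with a filter of 5 CPM (0.151) and with length and GC trends removed (0.0730). The NF-kB call was lost without control replicate 1 (adjusted p = 0.0746), without replicate 1 of the libraries labelled Fer knockdown (0.0604) and with a filter of 5 CPM (0.0518). With library totals alone the medians were 0.40 and 0.42, where that of all genes was 0.18. The mitochondrial share of counts was lower in the libraries labelled Fer knockdown. Both lists kept their calls with the mitochondrial chromosome left out, at medians of 0.22 and 0.23 (camera adjusted p = 0.0212 and 0.0153).

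Genes of G2 and mitosis were lower as a group. Of 25 tested, 0 passed over all genes, and 2 fell and 0 rose when adjusted over the list alone, with a median log2 fold change of -0.22 (camera adjusted p = 0.000773, and adjusted p = 0.443 with an estimated correlation). TPX2, a spindle assembly factor, went from 241 ± 15.3 to 171 ± 0.635 CPM (SD, n = 2 each), a log2 fold change of -0.50 ± 0.12 (SE, adjusted p = 0.0806), and the mitotic kinase PLK1 was at -0.52 (adjusted p = 0.0997, 12.5% exon overlap). The median was -0.06 with library totals alone, where that of all genes was 0.18. The mitochondrial share of counts was lower in the libraries labelled Fer knockdown (9.50% against 18.2%). With the mitochondrial chromosome left out the median was -0.23 and the call was kept (camera adjusted p = 0.000579). The 25 genes of S phase and DNA replication had a median of 0.07 (adjusted p = 0.629), with 0 past the test over all genes and 0 when adjusted over the list alone.

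**Figure D2:**
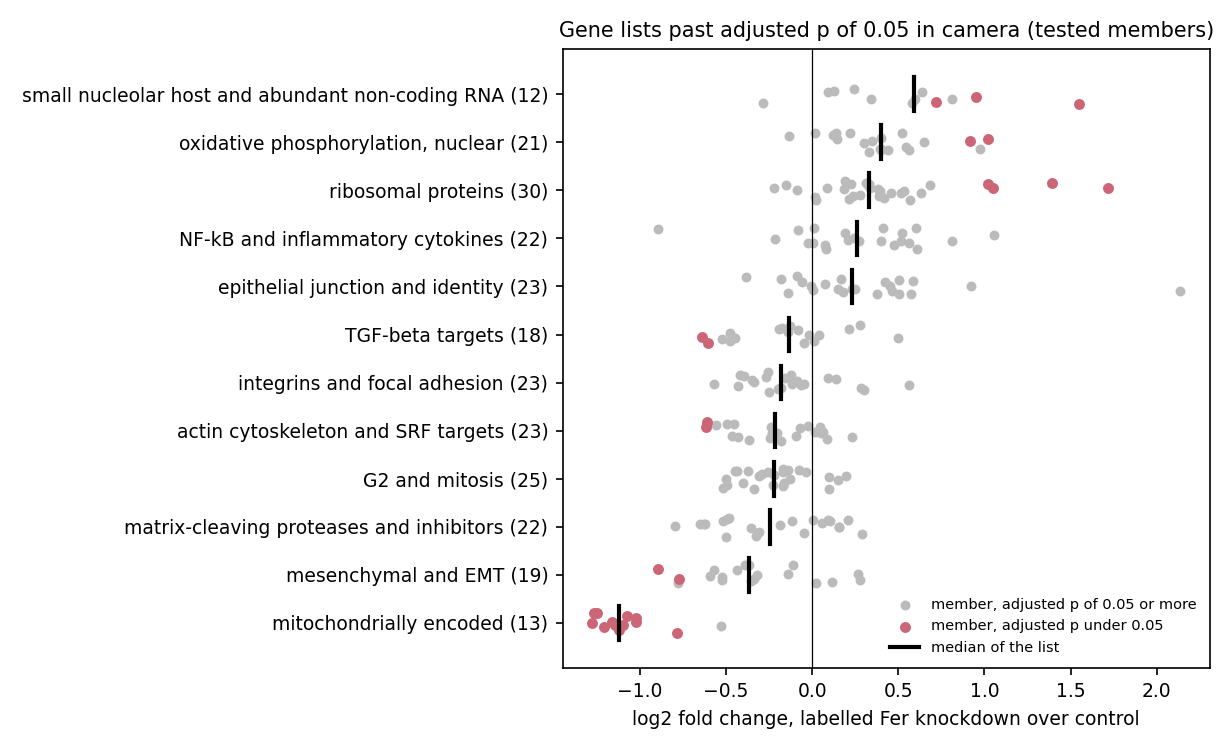
Log2 fold change of each tested member (points) of the 12 gene lists past an adjusted p of 0.05 in camera, with the list medians (bars) and the number of tested members in brackets. Points in red passed an adjusted p of 0.05 over all genes. The mitochondrially encoded list had a median of -1.12 and the non-coding RNA list one of 0.59.

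Among single genes, the largest increase by the fixed rule was in NELFE, a subunit of the negative elongation factor that pauses RNA polymerase II. NELFE (chromosome 6) went from 1.03 ± 0.412 to 17.6 ± 6.69 CPM (SD, n = 2 each), a log2 fold change of 4.10 ± 0.35 (SE, adjusted p = 0.00128). Its control level rests on 27 and 16 counts, and 4.89% of its exonic bases overlap other genes. TOMM7, of the mitochondrial import pore, rose by 1.60 (adjusted p = 0.0302) and COPS9, of the COP9 signalosome, by 1.42 (adjusted p = 0.0199). The acute-phase gene SAA1 rose by 1.54 (adjusted p = 0.0378, 6.41% exon overlap). NPR3, the natriuretic peptide clearance receptor, went from 8.51 ± 0.622 to 19.6 ± 0.277 CPM, a log2 fold change of 1.20 (adjusted p = 0.0182). LDHB, PARL and TXNDC12 rose by 1.65, 1.55 and 1.41 (adjusted p = 0.0354, 0.0302 and 0.0302), but 33.4%, 47.7% and 49.7% of their exonic bases overlap other genes. Outside the mitochondrial chromosome the largest decreases by the rule were in NPIPA5 (-1.13, adjusted p = 0.0200), NPIPB5 (-1.09, adjusted p = 0.0182, 20.6% exon overlap) and the non-coding RNA OLMALINC (-1.08, adjusted p = 0.0336). NPIPA5 and NPIPB5 belong to a family of near-identical duplicated genes on chromosome 16, so their counts are uncertain. Without replicate 2 of the libraries labelled Fer knockdown, LDHB, TXNDC12, NPIPA5, NPIPB5 and OLMALINC lost their calls (adjusted p = 0.0534, 0.0501, 0.152, 0.127 and 0.124). OLMALINC also lost its call without replicate 1 (adjusted p = 0.0751).

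**Figure D3:**
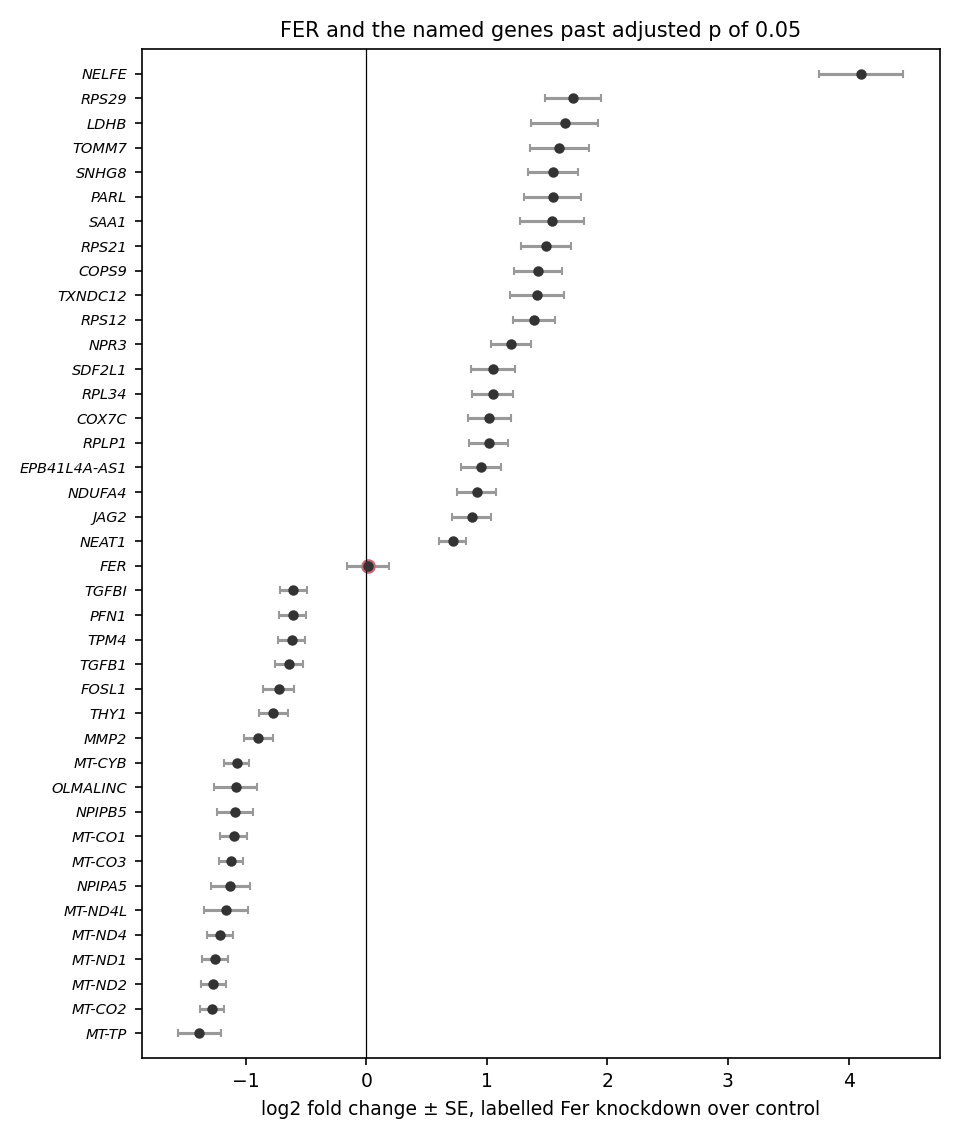
Log2 fold change with its SE for FER and for the 39 named genes past an adjusted p of 0.05, libraries labelled Fer knockdown over control, n = 2 each. FER lies at 0.02, NELFE at 4.10 and MT-TP at -1.38.

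The other 29 tested lists did not pass, with adjusted p from 0.0910 to 0.999 in camera. Single members passed in 3 of them. SDF2L1, a chaperone cofactor of the endoplasmic reticulum, rose by 1.05 (adjusted p = 0.0378) in the unfolded protein response list, in which 1 of 21 genes rose over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.0910). The ligand gene JAG2 rose by 0.87 (adjusted p = 0.0474) in the Notch list, in which 1 of 14 genes rose over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.182). FOSL1, a subunit of the transcription factor AP-1, fell by 0.73 (adjusted p = 0.0379) in the list of EGFR ligands and MAPK feedback genes, where 1 of 23 fell over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.529). FOSL1 and JAG2 lost their calls without replicate 1 of the libraries labelled Fer knockdown (adjusted p = 0.247 and 0.133) and, with SDF2L1, without replicate 2 (0.655, 0.334 and 0.125). Lists of p53 targets (adjusted p = 0.131), cholesterol synthesis (0.207), heat shock (0.223), dystroglycan glycosylation (0.370), collagens (0.629), STAT3 targets (0.629) and interferon response (0.734) did not pass. Nor did those of YAP and TEAD targets (0.901), NRF2 targets (0.961) and glycolysis and hypoxia (0.999). A mixed form of fry, which tests for change in either direction, passed 15 of the 41 tested lists. They included heat shock, iron handling, glycolysis, NRF2 and STAT3 targets (fry mixed adjusted p = 0.0340, 0.0171, 0.0173, 0.0140 and 0.0310). Adjusted over the list alone, heat shock had 1 higher and 3 lower, iron handling 1 and 2, glycolysis 0 and 2. The NRF2 and STAT3 lists had 0 either way. The median, mean and test differed in sign for lists of secretory cells, neuroendocrine cells, histones, metallothioneins, iron handling and NRF2 targets, none of which passed.

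Markers of other cell types gave no list past the test. The list of basal airway cells had a median of -0.16 over 14 tested genes (camera adjusted p = 0.725), with KRT17 at 0.77 (adjusted p = 0.0552) and ITGB4 at -0.44 (adjusted p = 0.0950). Lists of ciliated cells (8 tested, adjusted p = 0.633), secretory cells (5 tested, 0.629), alveolar cells (7 tested, 0.821), endothelial cells (7 tested, 0.901) and neuroendocrine cells (7 tested, 0.745) also did not pass. Of 17 leukocyte genes, 5 were tested, with a median of -0.27 (camera adjusted p = 0.148) and CD74 at -0.76 (adjusted p = 0.0560). Of 15 pluripotent cell markers 3 were expressed highly enough to be tested, and of 11 erythroid and platelet markers 0 were, so these lists were not tested.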

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

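All alternatives were planned except leaving out the mitochondrial chromosome and removing length and GC trends, which were chosen after seeing the data. FER did not pass in any of the 15 alternatives that gave it a value, with log2 fold changes from -0.16 without control replicate 1 to 0.19 without control replicate 2 and adjusted p from 0.369 to 1. All 99 genes called kept their sign in each alternative that gave them a value. In all 99 the libraries of the 2 groups did not overlap, so leaving out a library could hardly change a sign. A fit without a control takes the spread from the libraries labelled Fer knockdown alone, which differed less from each other.

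The correlation of deviations between libraries of the same number was 0.0373 over 2 pairs. With 2 libraries per group these pairs give a single value, which cannot settle whether the numbers pair the libraries. The median log2 difference of replicate 2 minus replicate 1 ran the same way along GC content in both groups. From genes under 40% GC to genes over 60% it went from 0.27 to -0.23 in control. In the libraries labelled Fer knockdown it went from 0.08 to -0.03. With the replicate number as a block the count of calls was 990 (537 higher, 453 lower), and all 99 were among them. With the block the integrin list missed the threshold (adjusted p = 0.052) and the list of the unfolded protein response and amino acid stress passed it as higher (adjusted p = 0.0483), which gave 6 lists higher and 6 lower. No other list or named gene called lost its call.

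Against 99 calls (43 higher, 56 lower), upper-quartile factors gave 192 (81 higher, 111 lower), library totals alone 443 (396 higher, 47 lower), DESeq2 583 (250 higher, 333 lower), limma-voom 178 (75 higher, 103 lower) and no filter on low counts 993 (526 higher, 467 lower). Removing length and GC trends gave 1104 (484 higher, 620 lower), and leaving out the mitochondrial chromosome 76 (41 higher, 35 lower), which by construction lacks 15 of the 56 lower genes. For the other counts the cause was not tested. Testing against a 1.5-fold change, a stricter hypothesis, gave 8 (2 higher, 6 lower). Leaving out a library gave 56 to 4734 calls (31 to 2344 higher, 25 to 2390 lower). DESeq2 size factors gave 132 and a filter of 5 CPM gave 117.

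Of the 12 lists past the threshold (5 higher, 7 lower), 0 passed with an estimated correlation (0 higher, 0 lower) and 0 with fry (0 higher, 0 lower). Over all 41 tested lists, fry gave 13 an unadjusted p under 0.05 and a lowest adjusted p of 0.102. Both tests use the 2 residual degrees of freedom. The estimated correlation was below the preset 0.01 for the mesenchymal, G2 and mitosis, NF-kB, epithelial and TGF-beta lists (-0.0444 to 0.00272). Their lost calls therefore do not come from a higher correlation between genes. It was far above the preset for ribosomal proteins (0.879), nuclear oxidative phosphorylation (0.733) and mitochondrially encoded genes (0.64). For the other lists past the threshold it ran from 0.0154 to 0.211. Leaving out a library left 9 to 17 lists past the threshold (4 to 5 higher, 5 to 12 lower). The list of YAP and TEAD targets, at a median of -0.02 (adjusted p = 0.901), passed in opposite directions without 1 control, at 0.0687 without control replicate 2 (adjusted p = 0.0480) and -0.0995 without control replicate 1 (adjusted p = 0.0428). Its adjusted p over all alternatives ran from 0.0428 to 0.989, and the cause was not tested. Without the mitochondrial chromosome PFN1, TPM4, TGFBI and JAG2 missed the threshold (adjusted p = 0.0515 to 0.0521). The depth of 21422976 to 25169713 counts limits genes of low expression. With 2 libraries per group the simulated recovery of 1.5-fold changes was 46.3%. That simulation changed only genes with an average log2 CPM above 2 and gave both groups the same spread.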

Other observations

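The genes in the first 2 paragraphs were chosen after their values were seen, as were the tests of a swapped label, of depth for FER, of scaling and of uniform loss for the mitochondrial genes, and of genes close in length and expression and of variation between libraries for the ribosomal genes. Among genes that fell in the libraries labelled Fer knockdown, ECM1, an extracellular matrix glycoprotein, went from 491 ± 26.9 to 278 ± 6.09 CPM (SD, n = 2 each), a log2 fold change of -0.82 ± 0.11 (SE, adjusted p = 0.0193). L1CAM, a neural cell adhesion molecule, fell by 0.67 (adjusted p = 0.0360, 11% exon overlap), and FXYD5, a regulator of the sodium pump, by 0.84 (adjusted p = 0.0205). The alpha-tubulin gene TUBA1C, whose counts are uncertain since 25% of its exonic bases overlap other genes and it has close paralogs, fell by 0.93 (adjusted p = 0.0227). SH3BGRL3 had the lowest adjusted p of the nuclear genes that fell, 0.0118, at -0.94 ± 0.11 (SE, 10.9% exon overlap). Without replicate 1 of the libraries labelled Fer knockdown, ECM1, L1CAM, FXYD5 and SH3BGRL3 lost their calls (adjusted p = 0.214, 0.428, 0.182 and 0.0561). Without replicate 2, these and TUBA1C did (adjusted p = 0.125 to 0.656).

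Among genes that rose, HES6, a transcriptional regulator related to the targets of Notch, went from 26 ± 3.93 to 54.5 ± 0.0606 CPM (SD, n = 2 each), a log2 fold change of 1.07 ± 0.15 (SE, adjusted p = 0.0193). GAS1, a surface co-receptor for hedgehog ligands, rose by 0.79 (adjusted p = 0.0474), the small Maf protein gene MAFK by 0.83 (adjusted p = 0.0302, 18.1% exon overlap) and the myeloid receptor gene TREM2 by 1.10 (adjusted p = 0.0436). CXCR1, a receptor for CXCL8, rose by 2.32 (adjusted p = 0.0182) from 0.857 to 4.29 CPM. GAS1 and MAFK lost their calls without replicate 1 of the libraries labelled Fer knockdown (adjusted p = 0.127 and 0.155), and GAS1, MAFK and TREM2 without replicate 2 (0.439, 0.356 and 0.125). The pseudogene ADORA2BP1 rose by 3.17 (adjusted p = 0.00421) from 1.78 to 16.0 CPM, while its parent ADORA2B was at 0.06 (adjusted p = 0.837). The control libraries differed along the GC content of transcripts, with a median log2 difference of replicate 2 minus replicate 1 of 0.27 over 1082 genes under 40% GC and -0.23 over 2717 genes over 60%. The same differences between the libraries labelled Fer knockdown were 0.08 and -0.03.

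FER mRNA did not differ in the libraries labelled Fer knockdown. If the shRNA lowered FER mRNA, a swap of 1 control with 1 knockdown would leave a library with little FER. The lowest library held 0.772 of the CPM of the highest (95% counting interval 0.670 to 0.889), and both were controls. If the shRNA left the mRNA unchanged, a swap would leave no such library, so the ratio cannot decide that case. Reads of other genes could add to FER, but 0.146% of its 50-base sequences (20 of 13696) occur in transcripts of other genes. Depth did not hide a 2-fold loss of the mRNA, since the lower limit of the log2 fold change was -0.37. Whether the shRNA ever acted, had lapsed or acted on the protein alone was not tested and stays open. The match of columns to samples was not tested beyond their names.

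The fall of mitochondrially encoded mRNAs was weighed against scaling, length and GC trends, and a loss in 1 proportion. A difference between libraries in selection on oligo(dT) beads or in RNA quality was not tested and stays open. Scaling does not account for it, since their median log2 change per read of other genes was -1.13. Removing length and GC trends left it at -1.15. With like selection on oligo(dT) beads, loss of all mitochondrial RNA in 1 proportion would keep the ratio of the ribosomal RNA MT-RNR2 to MT-CO2. The log2 ratio differed between the groups by 0.64, against at most 0.054 between replicates. If that selection differed between the groups, the ratio cannot decide on such a loss. MT-CO2 had the largest fall of the mitochondrial mRNAs past the threshold. The mRNA MT-ND6 was at -0.78, close to the ribosomal RNAs MT-RNR1 at -0.72 and MT-RNR2 at -0.64. The size of the gap thus depends on the mRNA chosen. The lower share of mitochondrial mRNAs in the libraries labelled Fer knockdown may be a biological difference. This is a hypothesis found and examined on the same 4 libraries. Counts are shares of a library, so amounts per cell were not measured. A link to FER was not tested, since FER mRNA did not differ.

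The higher level of ribosomal protein and nuclear respiratory chain genes as groups was weighed in the same way. A length trend would raise short transcripts of any kind, but 335 genes of like length had a median log2 change of -0.06 (95% bootstrap interval -0.09 to -0.03), against 0.38 (0.30 to 0.42) for the 51 list genes. Length was the median over a gene's annotated transcripts, not that of the expressed one. A trend confined to the shortest expressed mRNAs therefore stays open. Calls were more frequent among short transcripts, with 12 of 595 genes binned under 600 bases called, against 4 of 1990 over 4000. The median log2 changes of these bins were 0.04 and 0.01. Whether length accounts for single genes that rose was not tested. These 335 were less expressed (median log2 CPM of 7.35 against 8.61), but genes within 0.5 on the log2 scale of each list gene in both length and CPM (median log2 CPM of 8.54) had a median of -0.07 (-0.12 to -0.03). The bootstrap intervals were taken over genes and do not cover the spread between libraries. Variation between libraries that does not follow the labels cannot be told apart from an effect of the labels. The nearest control and knockdown libraries differed by 0.39 in the median log2 CPM of the list genes, while the 2 controls differed by 0.36 and the libraries labelled Fer knockdown by 0.01, and no biological explanation was tested.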
